A study of Mus musculus with 10 samples.

How the data were processed

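Small RNA was sequenced from the cortex of mouse embryos at embryonic day 13.5 in a line with a conditional knock-out of Dicer and a line with a conditional knock-out of DGCR8. Dicer is the enzyme that trims miRNA precursors to their mature length, and DGCR8 is the partner of Drosha in the nuclear step that frees the precursor from its primary transcript. The 10 libraries came from 5 groups with 2 mice each: Dicer wild type (Dicer WT), Dicer knock-out (Dicer KO), DGCR8 wild type (DGCR8 WT), DGCR8 heterozygote (DGCR8 HET) and DGCR8 knock-out (DGCR8 KO). Per the labels, libraries were made with a TruSeq small RNA kit from 1000 ng of total RNA. The driver of the deletion and the share of cells that lost the gene are not given in the sources used here.

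The deposited table holds raw read counts, with 19414 entries by 10 libraries. Each entry is a mature miRNA name with a 3′ suffix, which says either that no base was added or which 1 to 3 bases were. The table does not say whether an added base matches the genome. The submitters' processing notes name Bowtie and the mouse genome GRCm38, and the name of the deposited table names IsomiRage. The aligner version, the mismatch setting, the miRNA annotation and the treatment of reads with several matches are not given in the sources used here. For the DGCR8 line, a number in the table's column names that may mark a pool or run differs from that in the sample descriptions. Columns were matched to samples on line and index number, each of which belongs to a single sample, so every DGCR8 value rests on that match. Total sequenced reads per library were not used here, and depth below means reads assigned to miRNAs.

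Counts were summed over suffixes for each of 1432 mature miRNA names, and 1 entry name that occurs in more than one row was added to its miRNA. Of these names, 1249 had a read in at least 1 library and 557 passed edgeR's filterByExpr by group, with a minimum count of 10 and a minimum total of 15. Libraries held from 800623 to 4486774 miRNA reads, and the untested names took from 0.0297% to 0.0476% of them. Library scaling used TMM (trimmed mean of M values), so each change is relative to the other miRNAs of a library. No spike-in enters the scaling, and a loss shared by all miRNAs would not be seen. CPM below are edgeR's cpm values after TMM scaling, given as mean ± SD of 2 libraries.

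All 10 libraries were fitted together with 1 mean per group by edgeR's quasi-likelihood test, which estimates the spread over all 5 groups. The biological coefficient of variation was 0.23, with 5 residual and 4.2 prior degrees of freedom. The 6 contrasts tested were the knock-outs each against the wild type of their line, DGCR8 HET against DGCR8 WT, DGCR8 KO against DGCR8 HET, the DGCR8 KO effect minus the Dicer KO effect, and DGCR8 WT against Dicer WT. P-values are two-sided and adjusted by Benjamini-Hochberg over the 557 miRNAs of a contrast, and a miRNA was called changed at an adjusted p below 0.05. Log2 fold changes are given ± SE of the fit, with n = 2 libraries per group unless stated. The p-values measure differences between group means of 2 mice each, judged against a spread between mice that is pooled over all 5 groups. An exact two-sided permutation of 2 against 2 libraries cannot go below p = 0.333, so shares of reads are given as values without a test.

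Lists of miRNAs were tested with limma's camera on TMM log2 CPM at a preset correlation of 0.01, again with the correlation estimated, and with fry. Lists with at least 3 tested members entered, and p-values were adjusted over the lists of a contrast. The lists, with tested members, were DGCR8-independent miRNAs (24), mirtron-numbered miRNAs (21, miRBase numbers assigned in a survey of mirtrons), neuron-enriched miRNAs (22), miR-9 and miR-125 (7), the let-7 family (18), the miR-17-92 and paralog clusters (23), the 12qF1 imprinted cluster (78), vessel and blood miRNAs (14), choroid plexus and epithelial miRNAs (12) and the repeat family of miR-297, miR-466, miR-467 and miR-669 (19). The posterior Hox (2), muscle (1), pluripotency (2) and Dicer-independent (1) lists were too small for a list test. The tested posterior Hox members were miR-10a-5p and miR-10b-5p, the latter in introns of Hoxd3 and Hoxd4. The list name stands for tissue behind the forebrain, not for the posterior Hox genes. The lists overlap only in miR-451a, which is both the Dicer-independent list and a member of the vessel and blood list. A mesenchymal list, miR-199 and miR-214 (5 members), was chosen after seeing the data and was not given a list test. Cortex also holds vessels, blood and choroid plexus next to it, so members of those lists may be present in dissected cortex of any genotype.

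The contrasts, the lists, the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule named, per contrast, the 10 largest rises and the 10 largest falls among called miRNAs with a mean of at least 10 CPM and no overlap between the compared libraries. It also named the 10 most abundant miRNAs over the wild types and up to 4 tested members of each list by mean CPM. Of the miRNAs called between the knock-outs, miR-3535 and miR-6958-3p fall outside the rule in that contrast and were named after their values were seen. The same holds for the effects in each knock-out of the other miRNAs called there, which are given beside their difference. The share of reads with a single added T was taken over the 180 miRNAs with at least 100 reads in every library.

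Alternatives covered library totals alone, DESeq2 size factors, upper quartile factors, factors from the DGCR8-independent list or the vessel and blood list, DESeq2's Wald test, no filter on low counts, a filter of 10 CPM in 2 libraries, the lines fitted apart, the replicate number as a block, reads without additions only, each suffix entry tested alone, and leaving out each library. In the last, a group's lone library is assumed to vary like the other groups. The contrasts without DGCR8 HET replicate 2, where it is not among the compared libraries, the fit without the other-tissue lists, the numbers of miRNAs called in both knock-outs under each alternative, a single random thinning of every library to the smallest total, and the DGCR8-independent list without its miR-344 members were added after seeing the data. The fit was tested on simulated data with the real depths and group sizes and a spread pooled over groups, in 5 draws with 200 of 557 miRNAs changed. In the Dicer contrast 49.8% of 2-fold and 85.6% of 4-fold changes were recovered, with 3.84% of calls false. In the DGCR8 KO contrast these values were 47.6%, 85.4% and 2.64%, and in the contrast between the knock-outs 18.4%, 66.4% and 2.52%. The draws gave all groups the same spread. In the real data, chi-square over degrees of freedom between replicates differed, at 156.3 in Dicer WT and 11.98 in DGCR8 WT. How unequal spread changes the recovered and false shares was not tested, so these shares may not hold for the real data. Camera found a raised list of 24 in 20 of 20 draws and called 0 of 200 unchanged lists, at the preset and at the estimated correlation alike. The simulated miRNAs varied independently of each other. These draws therefore cannot show how often camera calls an unchanged list whose members vary together.

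Positions are those of the GENCODE vM21 annotation on GRCm38, matched by miRNA gene symbol, and miR-3535 has no locus under its symbol there. A miRNA is placed in an exon where its gene overlaps an exon of any annotated transcript. The same stretch may therefore be an intron in another transcript. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15. Transcripts of Dicer1 and Dgcr8 were not analysed here, and a table of mature miRNAs cannot show whether either gene was deleted. Reads were amplified and carry no molecular identifiers, so they are not independent molecules. The replicate number is shared between groups of a line without a stated pairing, and the fit with it as a block is given only among the alternatives.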

Results

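In the wild types of both lines miR-92a-3p and miR-9-5p took the largest shares of miRNA reads. The 10 most abundant miRNAs took from 53.0% to 61.0% of the miRNA reads of a library. The most abundant was miR-92a-3p in 8 libraries and miR-9-5p in DGCR8 WT replicate 2 and DGCR8 HET replicate 2. Dicer KO libraries held 983318 and 800623 miRNA reads, against 4006217 and 4486774 in Dicer WT, whose mean was 4.76 times that of the knock-out. DGCR8 KO libraries held 2011508 and 1535333, against 2608742 and 2420701 in DGCR8 WT, and DGCR8 HET held 2364463 and 2468929. Since the RNA put into a library was fixed and total reads were not used here, these totals do not measure miRNA per cell.

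**Figure D1:**
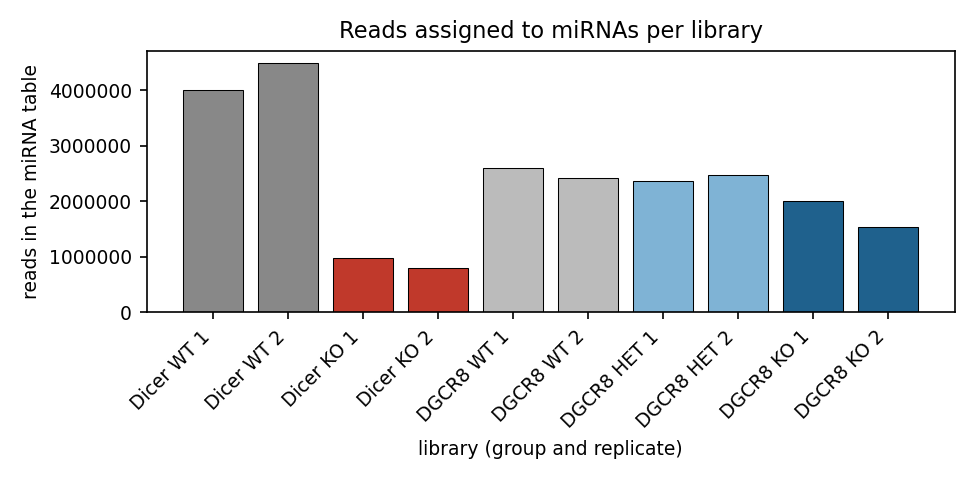
Reads assigned to miRNAs in each library (vertical axis, starting at 0), with 1 bar per library coloured by group. Dicer KO libraries lie at 983318 and 800623 reads, below all 8 other libraries.

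Dicer KO was compared with Dicer WT to ask which miRNAs of the cortex changed when the last processing enzyme was deleted conditionally. The let-7 family, which rises as neural progenitors mature and restrains growth genes, fell relative to the other miRNAs. let-7b-5p fell from 2248 ± 784 CPM to 450.5 ± 195.7 CPM (log2 fold change −2.32 ± 0.35, adjusted p = 0.00171). miR-92b-3p, abundant in cortical progenitors, fell from 86317 ± 10213 CPM to 26318 ± 1630 CPM (−1.71 ± 0.12, adjusted p = 6.61e-05). Endothelial miR-126a-3p rose (1.60 ± 0.26, adjusted p = 0.00220), as did smooth-muscle miR-143-3p (1.48 ± 0.28, adjusted p = 0.00483) and erythroid miR-486-5p (1.32 ± 0.16, adjusted p = 5.76e-04). In all, 172 of 557 miRNAs changed, 83 higher and 89 lower, and 60 of the higher and 54 of the lower ones by more than 2-fold.

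Of the 18 tested members of the let-7 family, 17 fell, 0 rose and 1 was not called, with 17 falls when adjusted over the list alone. The median log2 fold change of the family was −1.60, a fold of 3.03 downward, at an adjusted p = 5.25e-09, and adjusted p = 0.228 with an estimated correlation. Its abundant members let-7f-5p (−0.96 ± 0.18, adjusted p = 0.00492) and let-7c-5p (−1.05 ± 0.19, adjusted p = 0.00324) fell less than let-7b-5p. The miR-17-92 and paralog clusters, tied to proliferation, had 7 falls and 1 rise among 23, and the same when adjusted over the list alone (median −0.43, adjusted p = 0.0202; adjusted p = 0.305 with an estimated correlation). Without Dicer WT replicate 1 the median of that list was −0.32 and the adjusted p = 0.0958. Of miR-9 and miR-125, 3 of 7 fell and 0 rose, or 3 and 1 when adjusted over the list alone (median −0.34, adjusted p = 0.195), among them miR-9-5p (−0.86 ± 0.17, adjusted p = 0.00522). The abundant miR-92a-3p (−0.10 ± 0.10, adjusted p = 0.469), miR-181a-5p (−0.0651 ± 0.13, adjusted p = 0.699) and miR-26a-5p (0.27 ± 0.12, adjusted p = 0.126) were not called, the last being called higher on library totals (0.50, adjusted p = 0.00515). Among the 22 neuron-enriched miRNAs 3 rose and 2 fell, or 2 and 2 when adjusted over the list alone (median 0.25, adjusted p = 0.420). One of these was miR-218-5p, of motor and other neurons, which fell (−1.23 ± 0.26, adjusted p = 0.00704), while miR-124-3p (0.51 ± 0.24, adjusted p = 0.138) and miR-128-3p (−0.68 ± 0.34, adjusted p = 0.147) were not called in the main fit. miR-124-3p was called higher in reads without additions (1.18, adjusted p = 0.0123) and on library totals (0.74, adjusted p = 0.0479). miR-128-3p was called lower in reads without additions (−0.93, adjusted p = 0.0428), with the replicate block (−0.80, adjusted p = 0.0223) and with no filter on low counts (−0.89, adjusted p = 8.33e-06).

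The 12qF1 imprinted cluster, a large maternally expressed group of miRNAs, had 31 rises and 0 falls among 78 tested members, and 38 rises when adjusted over the list alone. Its median was 0.79, a fold of 1.73, at an adjusted p = 1.51e-13, and adjusted p = 0.231 with an estimated correlation. Examples are miR-127-3p (0.89 ± 0.15, adjusted p = 0.00278) and miR-434-3p (0.90 ± 0.19, adjusted p = 0.00759). The cluster took 3.41% and 2.53% of miRNA reads in Dicer WT and 5.76% and 6.99% in Dicer KO. Of the 14 vessel and blood miRNAs, 10 rose and 0 fell, with 12 rises when adjusted over the list alone (median 1.44, a fold of 2.71, adjusted p = 3.92e-06; adjusted p = 0.231 with an estimated correlation). These miRNAs took 1.27% and 1.02% of reads in Dicer WT and 3.36% and 3.95% in Dicer KO. The myeloid miR-223-3p was among them (1.99 ± 0.41, adjusted p = 0.00667). So was miR-451a, the single member of the Dicer-independent list, which is trimmed by AGO2 in place of Dicer in red cells (1.36 ± 0.29, adjusted p = 0.00819). Scaled to the vessel and blood list, which moved the median of all miRNAs by −1.44, the median of the 12qF1 cluster turned to −0.65.

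miRNAs of other tissues were followed next to the vessel and blood list, and few of them were called in Dicer KO. Both tested posterior Hox miRNAs rose, and both when adjusted over the list alone (median 1.80), among them miR-10b-5p (1.97 ± 0.51, adjusted p = 0.0187). The single tested muscle miRNA, miR-133a-3p, rose (2.14 ± 0.45, adjusted p = 0.00759), but in reads without additions it lay at 0.27 (adjusted p = 0.830). Of 12 choroid plexus and epithelial miRNAs 1 rose, miR-34b-3p (2.26 ± 0.63, adjusted p = 0.0246), and 0 fell, with 0 calls when adjusted over the list alone (median 0.48, adjusted p = 0.412). That list took 0.333% and 0.923% of reads in the Dicer WT mice and 0.784% and 2.04% in the Dicer KO mice, so mice of one genotype differed by more than 2-fold. The 5 mesenchymal miRNAs had 0 calls (median 1.499) and took 0.104% and 0.0650% of reads in Dicer WT and 0.212% and 0.397% in Dicer KO. Of 2 pluripotency miRNAs 0 were called, and 1 rose when adjusted over the list alone (median 1.13). The repeat family, whose near-identical copies make its counts uncertain, had 1 rise and 0 falls among 19, and 0 when adjusted over the list alone (median 0.38, adjusted p = 0.193). Scaled to the vessel and blood list, the medians of the neuron-enriched, choroid and repeat lists turned to −1.20, −1.04 and −1.07.

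miRNAs described as made without DGCR8 come from mirtrons, capped hairpins and other small RNAs that skip the nuclear step and still need Dicer. In Dicer KO 6 of 24 fell and 2 rose, or 7 and 2 when adjusted over the list alone (median −0.62, adjusted p = 0.0235; adjusted p = 0.209 with an estimated correlation). Without Dicer KO replicate 2 the median was −0.43 and the adjusted p = 0.0530. Their share of reads went from 0.561% and 0.540% to 0.361% and 0.375%. The capped-hairpin miR-484 fell from 3381 ± 34.9 CPM to 1811 ± 33.8 CPM (−0.90 ± 0.12, adjusted p = 8.33e-04), and the tRNA-derived miR-1983 fell as well (−1.52 ± 0.16, adjusted p = 2.62e-04). Of 21 mirtron-numbered miRNAs 5 fell and 0 rose, and the same when adjusted over the list alone (median −0.97, adjusted p = 5.75e-04; adjusted p = 0.141 with an estimated correlation). Among them was miR-6944-3p, from an intron of Dbn1 (−1.38 ± 0.15, adjusted p = 2.62e-04).

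Among called miRNAs with a mean of at least 10 CPM and no overlap between the compared libraries, the largest rises in Dicer KO were those of miR-3535 (4.58 ± 0.46, adjusted p = 2.62e-04), from 0.811 ± 0.0364 CPM to 20.4 ± 4.96 CPM, and of miR-3473b (4.05 ± 0.44, adjusted p = 2.62e-04). Smaller rises were those of miR-1247-3p (2.72), miR-6538 (2.69), miR-379-3p of the 12qF1 cluster (2.22) and miR-344d-3p (2.15). Within the same limits the largest falls were those of miR-3093-5p (−3.46 ± 0.40, adjusted p = 3.88e-04), miR-1251-5p (−2.87 ± 0.27, adjusted p = 2.62e-04) and miR-330-3p (−2.58 ± 0.30, adjusted p = 3.88e-04). miR-3081-3p (−2.51), miR-98-3p (−2.50), miR-670-3p (−2.34) and let-7i-3p (−2.15) followed. Both arms of miR-708, from an intron of Tenm4, fell, miR-708-5p from 993 ± 122 CPM to 211.7 ± 47.9 CPM (−2.23 ± 0.20, adjusted p = 2.62e-04) and miR-708-3p by a like amount (−2.18 ± 0.34, adjusted p = 0.00182).

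The share of miRNAs called, 30.9%, was 22.98% without Dicer WT replicate 1, 17.4% without Dicer WT replicate 2, 33.8% without Dicer KO replicate 1 and 23.2% without Dicer KO replicate 2. Of 38 called miRNAs named for this contrast, 30 kept their call in each of these omissions. miR-1247-3p (adjusted p up to 0.102), miR-34b-3p (0.206), miR-344d-3p (0.139), miR-133a-3p (0.0531), miR-10b-5p (0.102), miR-434-3p (0.0536), miR-451a (0.0584) and miR-6958-3p (0.217) did not. The highest of these p-values came without Dicer WT replicate 2 for miR-10b-5p, miR-434-3p and miR-451a, without Dicer KO replicate 1 for miR-1247-3p and miR-133a-3p, and without Dicer KO replicate 2 for the rest. Thinned to 800623 reads in every library, a setting added after seeing the data, 67 of 436 miRNAs were higher and 71 lower. The split into higher and lower depended on scaling: 48.3% of the 172 calls were higher, library totals gave 67.0% of 188 and moved the median of all miRNAs by 0.23, while factors from the vessel and blood list gave 4 higher and 348 lower and moved it by −1.44. With the lines fitted apart 19.03% of miRNAs were called, and each suffix entry tested alone gave 645 calls among 2169 entries.

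DGCR8 KO was compared with DGCR8 WT to ask the same of the nuclear processing step. miR-708-3p (−2.68 ± 0.34, adjusted p = 0.00297) and miR-708-5p (−2.12 ± 0.20, adjusted p = 5.34e-04) fell, the latter from 852 ± 92.9 CPM to 196.1 ± 7.22 CPM. miR-23a-3p, of a cluster on chromosome 8 tied to muscle and glia, fell from 278 ± 19.5 CPM to 74.3 ± 3.86 CPM (−1.90 ± 0.19, adjusted p = 6.93e-04). Its cluster partners miR-24-2-5p (−1.83 ± 0.24, adjusted p = 0.00305) and miR-27a-3p (−1.52 ± 0.24, adjusted p = 0.00911) fell too. miR-92b-3p fell from 50668 ± 3111 CPM to 18673 ± 1523 CPM (−1.44 ± 0.12, adjusted p = 2.84e-04). Changes were called for 115 of 557 miRNAs, 49 higher and 66 lower, with 27 of the higher and 24 of the lower ones over 2-fold.

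The 12qF1 imprinted cluster rose here too, with 27 rises and 0 falls among 78, and 43 rises when adjusted over the list alone (median 0.78, a fold of 1.72, adjusted p = 1.36e-19; adjusted p = 0.168 with an estimated correlation). It took 4.05% and 3.39% of reads in DGCR8 WT and 8.76% and 7.44% in DGCR8 KO, and miR-127-3p (0.73 ± 0.15, adjusted p = 0.0153) and miR-434-3p (0.71 ± 0.19, adjusted p = 0.0357) are examples. The DGCR8-independent miRNAs had 4 rises and 0 falls among 24, and the same when adjusted over the list alone (median 0.54, adjusted p = 7.61e-05; adjusted p = 0.0525 with an estimated correlation). Of the 24, 23 had a fold change above 0, and their share of reads went from 0.551% and 0.544% to 0.908% and 0.927%. In the main fit the 4 rises were all of the miR-344 family, and without its 6 members the median of the list was 0.40 (adjusted p = 0.00556; adjusted p = 0.168 with an estimated correlation). miR-344-3p rose (1.03 ± 0.16, adjusted p = 0.00911), while miR-484 (0.17 ± 0.12, adjusted p = 0.316), miR-1983 (0.30 ± 0.15, adjusted p = 0.199) and miR-320-3p (0.45 ± 0.17, adjusted p = 0.0894) were not called in the main fit. All 3 were called higher on library totals (0.59, 0.71 and 0.86, adjusted p = 0.0113, 0.0123 and 0.0130), with the lines fitted apart (0.34, 0.46 and 0.61) and in thinned libraries (0.39, 0.54 and 0.71), miR-1983 and miR-320-3p also in DESeq2 (0.40 and 0.55) and miR-320-3p in reads without additions (0.87, adjusted p = 0.0352). Of 21 mirtron-numbered miRNAs 2 rose and 0 fell, and the same when adjusted over the list alone (median 0.48, adjusted p = 0.0146; adjusted p = 0.168 with an estimated correlation). One was miR-6944-3p (0.56 ± 0.15, adjusted p = 0.0310). Without DGCR8 KO replicate 2 the mirtron-numbered median was 0.43 and the adjusted p = 0.0568.

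The let-7 family fell, with 8 falls and 0 rises among 18, and 13 falls when adjusted over the list alone (median −0.77, a fold of 1.71 downward, adjusted p = 1.23e-05; adjusted p = 0.271 with an estimated correlation). let-7f-5p fell (−0.73 ± 0.18, adjusted p = 0.0284) but was not called on library totals (−0.32, adjusted p = 0.172) or in thinned libraries (−0.50, adjusted p = 0.0823), and let-7c-5p was not called (−0.42 ± 0.18, adjusted p = 0.134). The miR-17-92 and paralog clusters had 6 falls and 0 rises among 23, and the same when adjusted over the list alone (median −0.43, adjusted p = 2.77e-04; adjusted p = 0.168 with an estimated correlation), with miR-92a-3p among them (−0.63 ± 0.10, adjusted p = 0.00911). It was not called on library totals (−0.22, adjusted p = 0.155) or in reads without additions (−0.55, adjusted p = 0.0536). Of miR-9 and miR-125, 2 of 7 fell and 0 rose, or 3 and 0 when adjusted over the list alone (median −0.31, adjusted p = 0.0494; adjusted p = 0.364 with an estimated correlation). miR-9-5p was one of them (−0.84 ± 0.17, adjusted p = 0.0144), but not on library totals (−0.43, adjusted p = 0.0600). Library totals turned the median of miR-9 and miR-125 to 0.10, and leaving out DGCR8 WT replicate 2 or DGCR8 KO replicate 1 gave an adjusted p = 0.0722 or 0.113. The abundant miR-26a-5p fell (−0.45 ± 0.12, adjusted p = 0.0375) but lay at −0.0359 on library totals (adjusted p = 0.792), and miR-181a-5p was not called (−0.15 ± 0.13, adjusted p = 0.394).

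Among the 22 neuron-enriched miRNAs 4 rose and 3 fell, and the same when adjusted over the list alone (median 0.39, adjusted p = 0.0544). miR-129-1-3p rose (1.26 ± 0.30, adjusted p = 0.0255), miR-218-5p fell (−1.22 ± 0.25, adjusted p = 0.0153), and miR-124-3p (0.28 ± 0.24, adjusted p = 0.403) and miR-128-3p (−0.62 ± 0.33, adjusted p = 0.217) were not called. On library totals miR-218-5p lost its call (−0.79, adjusted p = 0.0542), and miR-129-1-3p lost its call in thinned libraries (0.90, adjusted p = 0.230). miR-128-3p was called lower with the lines fitted apart (−0.46, adjusted p = 0.0134) and with no filter (−0.58, adjusted p = 0.0123). Of the 14 vessel and blood miRNAs 2 rose and 0 fell, with 0 calls when adjusted over the list alone (median 0.36, adjusted p = 0.0544). miR-143-3p (0.48 ± 0.28, adjusted p = 0.247), miR-486-5p (0.14 ± 0.16, adjusted p = 0.546) and miR-451a (0.84 ± 0.30, adjusted p = 0.0710) were not called in the main fit. miR-451a was called higher on library totals (1.26, adjusted p = 0.0205), with no filter (0.89), with the lines fitted apart (1.01), in thinned libraries (1.11) and in DESeq2 (0.95), and miR-143-3p on library totals (0.89) and with no filter (0.52). The list took 0.611% and 0.610% of reads in DGCR8 WT and 1.08% and 0.966% in DGCR8 KO. Of 12 choroid plexus and epithelial miRNAs 1 rose and 0 fell, with 0 calls when adjusted over the list alone (median 0.56, adjusted p = 0.456), at 0.127% and 0.134% of reads in DGCR8 WT and 0.330% and 0.136% in DGCR8 KO, and its median was −0.28 without DGCR8 KO replicate 1. The neuron-enriched call was gained without DGCR8 KO replicate 2 (median 0.46, adjusted p = 0.0369). The posterior Hox (median 1.09), pluripotency (0.78), repeat (0.26, adjusted p = 0.0725) and mesenchymal (0.94) lists had 0 calls, also when adjusted over the list alone, and the muscle miR-133a-3p rose (1.51 ± 0.43, adjusted p = 0.0403), but was not called in reads without additions (1.35, adjusted p = 0.173). The repeat list was called without DGCR8 WT replicate 1 (median 0.42, adjusted p = 0.0328) and without DGCR8 KO replicate 2 (median 0.46, adjusted p = 0.0136).

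Among called miRNAs with a mean of at least 10 CPM and no overlap between the compared libraries, the largest rise was that of miR-455-3p, from 8.74 ± 1.68 CPM to 77.7 ± 7.19 CPM (3.15 ± 0.82, adjusted p = 0.0313). In Dicer WT this miRNA lay at 233 and 28.3 CPM in the 2 mice, so the fit's spread for it is wide. miR-344d-3p (1.69), miR-344f-5p (1.53) and miR-344f-3p (1.47 ± 0.28, adjusted p = 0.0126), all of the DGCR8-independent list, rose, as did miR-409-5p (1.58) and miR-770-3p (1.56) of the 12qF1 cluster, miR-146a-5p (1.48) and miR-551b-3p (1.30). Within these limits the other largest falls were those of miR-3093-5p (−2.04), miR-3081-3p (−1.94), miR-193a-3p (−1.63) and miR-1251-5p (−1.49).

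Leaving out a library lowered the count to 19 without DGCR8 WT replicate 1, 5 without DGCR8 WT replicate 2, 13 without DGCR8 KO replicate 1 and 8 without DGCR8 KO replicate 2. Of the 31 called miRNAs named for this contrast, miR-708-3p, miR-708-5p, miR-23a-3p, miR-24-2-5p and miR-92b-3p kept their call in each of these omissions, and the others lost it in at least 1, with an adjusted p of up to 0.236. The split depended on scaling: library totals gave 105 higher and 14 lower with the median of all miRNAs moved by 0.41, DESeq2 size factors gave 61 and 47 (0.10), and upper quartile factors gave 50 and 42. With factors from the DGCR8-independent list 7.64% of 157 calls were higher (−0.32), and those from the vessel and blood list gave 2 and 37 (−0.33). With every library thinned to 800623 reads, 60 of 436 miRNAs were higher and 26 lower (0.18). With the lines fitted apart 158 miRNAs, or 28.4%, were called, 84 higher and 74 lower. The share in Dicer KO was then 19.03%, so which knock-out had more calls depended on whether the lines shared a fit.

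DGCR8 HET was compared with DGCR8 WT to ask whether the loss of 1 copy changed the miRNA pool. Progenitor miR-9-5p (−0.0147 ± 0.17, adjusted p = 0.993), miR-92b-3p (0.0190 ± 0.11, adjusted p = 0.993) and neuronal miR-124-3p (−0.23 ± 0.24, adjusted p = 0.993) were not called. edgeR called 0 of 557 miRNAs, with 23 at an unadjusted p below 0.05 where 27.85 would be found by chance, and DESeq2 called 0 as well. The lowest adjusted p was 0.858. Without DGCR8 HET replicate 1 there were 13 calls, all higher, and with no filter on low counts there were 18, all higher. The other-tissue lists lay higher in replicate 2: the choroid plexus and epithelial miRNAs took 0.104% of reads in replicate 1 and 0.560% in replicate 2, a ratio of 5.39. The mesenchymal miRNAs took 0.00440% and 0.0444%, a ratio of 10.1, and miR-199b-3p lay at 26.6 and 277 CPM (2.72 ± 0.86, adjusted p = 0.858). The vessel and blood miRNAs took 0.602% and 0.970%, while the 12qF1 cluster took 4.57% and 3.80%.

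Raised medians in DGCR8 HET were found for the 12qF1 cluster (0.21, adjusted p = 1.40e-04), the vessel and blood list (0.65, adjusted p = 5.46e-04) and the choroid plexus and epithelial list (0.99, adjusted p = 5.46e-04), each at an adjusted p = 0.565 with an estimated correlation. When adjusted over the list alone, 0 members of the 12qF1 and vessel lists and 3 of the choroid list were called. Without DGCR8 HET replicate 2 the vessel median was 0.0184 and the choroid median 0.16, each with an adjusted p = 0.929. The 12qF1 median was 0.0887 without DGCR8 WT replicate 2 (adjusted p = 0.845) and 0.0698 without DGCR8 HET replicate 1 (adjusted p = 0.929). The neuron-enriched list was called without DGCR8 HET replicate 1 (median −0.22, adjusted p = 0.00150). The other lists with a test had adjusted p from 0.0664 to 0.681. The posterior Hox median was 1.53 with 1 call when adjusted over the list alone, and the muscle and pluripotency values were 0.64 and 0.34. The mesenchymal median was 3.26, with 0 calls over all miRNAs. Its 5 calls when adjusted over the list alone are no test, since the list was chosen on these data. The mesenchymal share was 0.00440% in replicate 1 and 0.0444% in replicate 2, against 0.00337% and 0.00297% in DGCR8 WT.

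DGCR8 KO was set against DGCR8 HET as a further control group of the line. Falls were called for miR-23a-3p (−1.92 ± 0.19, adjusted p = 9.56e-04), miR-708-5p (−1.75 ± 0.20, adjusted p = 0.00160) and miR-92b-3p (−1.46 ± 0.12, adjusted p = 2.55e-04), each kept in every omission of a compared library. Of 557 miRNAs 48 changed, 11 higher and 37 lower. Falls were called too for miR-708-3p (−2.28), miR-3093-5p (−1.66), miR-24-2-5p (−1.65), miR-27a-3p (−1.50), miR-3081-3p (−1.37), miR-135a-2-3p (−1.30) and miR-1251-5p (−1.27). Rises were called for miR-337-5p (1.64), miR-409-5p (1.37), miR-376b-3p (0.81), miR-3071-3p (0.80), miR-381-3p (0.75) and miR-127-3p (0.56) of the 12qF1 cluster, for neuronal miR-129-1-3p (1.54) and miR-137-3p (1.11), for miR-344-3p (0.96) and for miR-6958-3p (1.20). These others lost their call in at least 1 omission, with an adjusted p of up to 0.262.

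The list medians in DGCR8 KO against DGCR8 HET were 0.57 for the 12qF1 cluster (6 rises, 0 when adjusted over the list alone, adjusted p = 7.55e-16; adjusted p = 0.231 with an estimated correlation) and −0.80 for the let-7 family (5 falls, 15 when adjusted over the list alone, adjusted p = 7.87e-06; adjusted p = 0.231 with an estimated correlation). The DGCR8-independent median was 0.54 (1 rise, also over the list alone, adjusted p = 7.60e-05; adjusted p = 0.0525 with an estimated correlation) and the mirtron-numbered median 0.34 (1 rise, also over the list alone, adjusted p = 0.0109; adjusted p = 0.209 with an estimated correlation). The neuron-enriched median was 0.50 (2 rises and 1 fall, 3 and 1 over the list alone, adjusted p = 0.00371; adjusted p = 0.231 with an estimated correlation). The medians of miR-9 and miR-125 (−0.37, adjusted p = 0.0411) and of the miR-17-92 and paralog clusters (−0.35, adjusted p = 0.00340) turned to 0.0310 and 0.0445 on library totals, and had adjusted p = 0.309 and 0.231 with an estimated correlation. The vessel (−0.24, adjusted p = 0.763), choroid (−1.25, adjusted p = 0.236) and repeat (0.24, adjusted p = 0.207) lists were not called, the vessel and choroid medians having the other sign than against DGCR8 WT, but the vessel median was 0.44 without DGCR8 HET replicate 2 (adjusted p = 0.00775). The choroid list was called without DGCR8 HET replicate 1 (median −1.99, adjusted p = 0.00109) and lay at 0.42 without replicate 2, and the repeat list was called without DGCR8 KO replicate 2 (median 0.39, adjusted p = 0.0369). The neuron-enriched call was lost without DGCR8 HET replicate 2 (adjusted p = 0.0570), the mirtron-numbered call without DGCR8 KO replicate 2 (adjusted p = 0.0792), and that of miR-9 and miR-125 without DGCR8 HET replicate 1 (adjusted p = 0.0933) or DGCR8 KO replicate 1 (adjusted p = 0.107). The number of miRNAs called fell to 7 without DGCR8 HET replicate 2, 5 without DGCR8 KO replicate 1 and 6 without DGCR8 KO replicate 2, and was 54 without DGCR8 HET replicate 1. Library totals gave 67 higher and 9 lower (median of all miRNAs moved by 0.41), DESeq2 size factors 23 and 31 (0.12), upper quartile factors 9 and 19, and DESeq2's test called 81. With factors from the DGCR8-independent list 23.7% of miRNAs were called, 4.55% of these higher (−0.29), against 8.62% and 22.9% in the full fit. With every library thinned to 800623 reads, 7 of 436 miRNAs were higher and 8 lower (0.13).

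Dicer KO and DGCR8 KO changed many of the same miRNAs, each against the wild type of its own line. Of the miRNAs called in both, 28 were higher in both knock-outs, where 7.30 would be shared by chance, and 37 were lower in both, where 10.5 would be. Only 1 was higher in Dicer KO and lower in DGCR8 KO, and 2 the reverse. The numbers given for chance treat miRNAs as independent draws. Most of those higher in both belong to the large imprinted cluster, and some of those lower in both share a family. Such miRNAs can move together, so the numbers given for chance are no test of how broad the overlap is. The shared numbers depended on the DGCR8 libraries: higher in both were 3 without DGCR8 WT replicate 1, 0 without DGCR8 WT replicate 2, 0 without DGCR8 KO replicate 1 and 1 without DGCR8 KO replicate 2, and lower in both 11, 3, 8 and 3. Without Dicer WT replicate 2 there were 13 higher in both, library totals gave 55 higher and 9 lower, libraries thinned to 800623 reads 27 and 18, and factors from the vessel and blood list 1 and 35. Progenitor miR-92b-3p, both arms of miR-708, miR-3093-5p and miR-1251-5p are among those lower in both, and miR-127-3p and miR-434-3p among those higher in both. Across the 557 miRNAs, which are not independent replicates, the 2 effects had Pearson's r of 0.536 and Spearman's rho of 0.524 (permutation p = 1e-05, the smallest the permutations can give, in this single relation). The effects had the same sign for 71.8% of miRNAs.

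**Figure D2:**
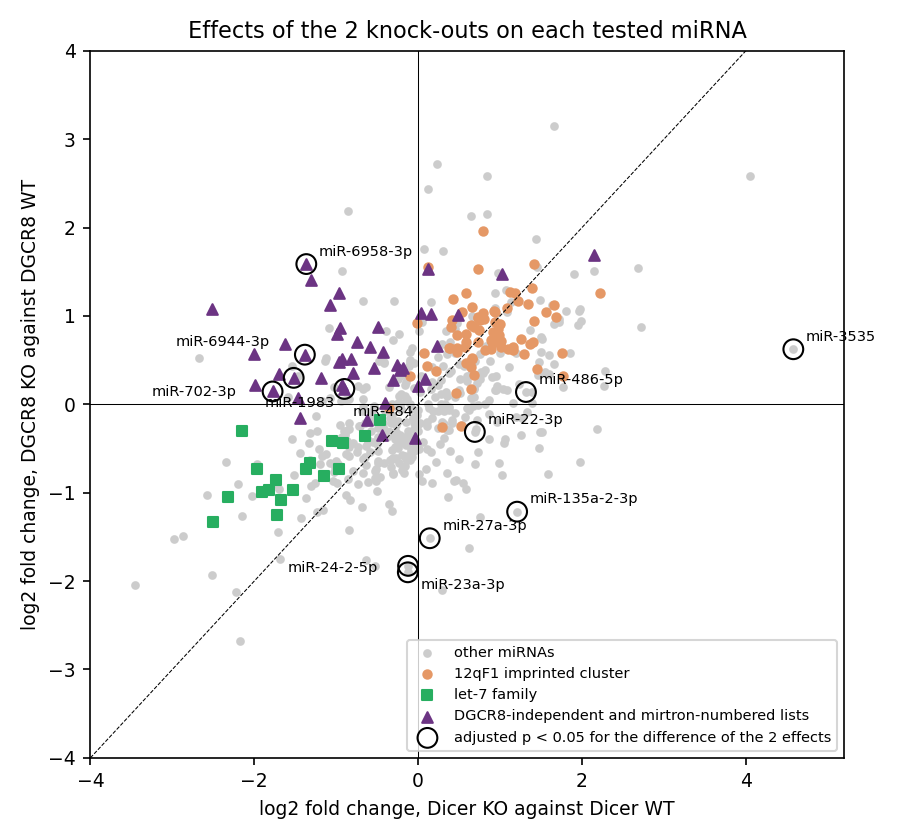
Log2 fold change in Dicer KO against Dicer WT (horizontal axis) and in DGCR8 KO against DGCR8 WT (vertical axis) for each of 557 miRNAs, with the 12qF1 cluster (orange), the let-7 family (green) and the DGCR8-independent and mirtron-numbered lists (purple) marked, and the 12 miRNAs called for the difference circled. The effects follow each other across miRNAs (r of 0.536), while miR-484 (−0.90 and 0.17), miR-1983 (−1.52 and 0.30) and miR-6944-3p (−1.38 and 0.56) lie above the line of equal effects.

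**Figure D3:**
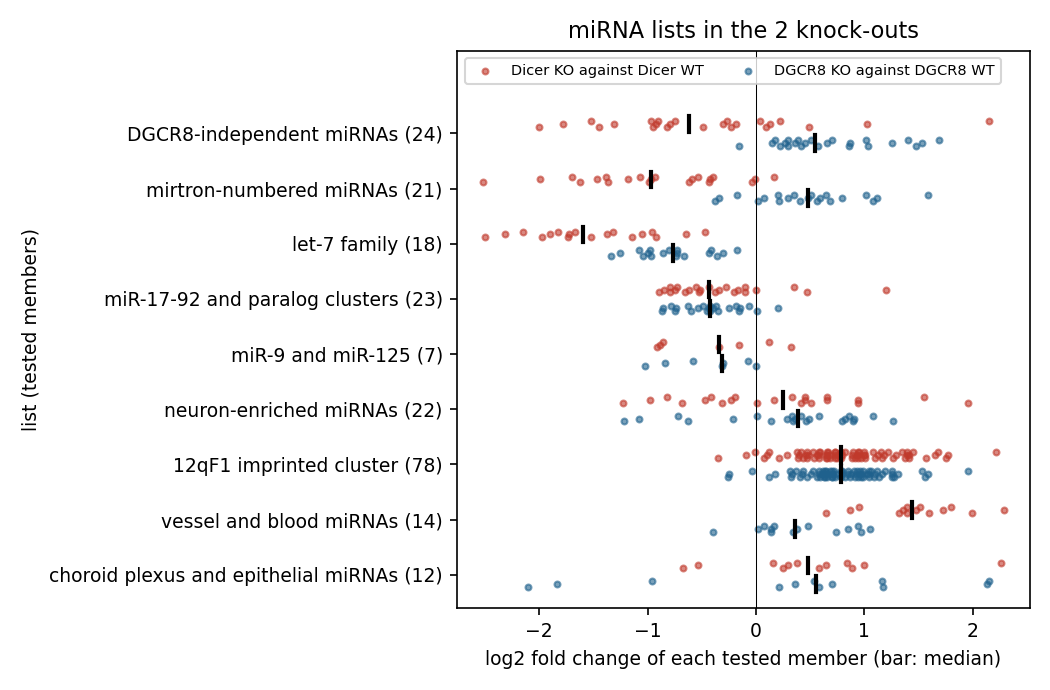
Log2 fold change of each tested member of 9 lists in Dicer KO (red) and DGCR8 KO (blue), each against its wild type, with bars at the medians. The DGCR8-independent medians are −0.62 and 0.54 and those of the 12qF1 cluster 0.79 and 0.78; scaled to the vessel and blood list the Dicer KO medians of the 12qF1, neuron-enriched and choroid lists turned to −0.65, −1.20 and −1.04, and on library totals the DGCR8 KO median of miR-9 and miR-125 turned to 0.10.

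The difference between the knock-outs was tested as the DGCR8 KO effect minus the Dicer KO effect, which asks which miRNAs depend on one step more than on the other. The DGCR8-independent miRNAs stood out, with a median difference of 1.15, a fold of 2.22, and 23 of 24 members above 0 (adjusted p = 3.83e-09). This list kept its call with an estimated correlation (adjusted p = 0.00891). It had 3 called members, all higher, and 10 when adjusted over the list alone, and its median stayed between 1.01 and 1.25 when each compared library was left out. The mirtron-numbered miRNAs had a median of 1.45, with 20 of 21 above 0 (adjusted p = 4.97e-08; adjusted p = 0.0108 with an estimated correlation), 2 called members and 8 when adjusted over the list alone. With each compared library left out their median lay between 1.30 and 1.74.

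Of 557 miRNAs 12 differed between the knock-outs, 5 higher and 7 lower. Among those higher were miR-6944-3p (1.94 ± 0.21, adjusted p = 0.00292), miR-1983 (1.82 ± 0.22, adjusted p = 0.00425) and miR-484 (1.07 ± 0.17, adjusted p = 0.0122). Another was miR-702-3p, whose gene overlaps an exon of at least 1 annotated transcript of Plod3 (1.92 ± 0.31, adjusted p = 0.0122, with −1.78 in Dicer KO and 0.15 in DGCR8 KO). The fifth was miR-6958-3p (2.95 ± 0.48, adjusted p = 0.0124; −1.36 and 1.59), whose lowest count was 2 reads. Among those lower were the 3 miRNAs of the cluster on chromosome 8: miR-23a-3p (−1.77 ± 0.27, adjusted p = 0.0122), miR-24-2-5p (−1.70 ± 0.33, adjusted p = 0.0314) and miR-27a-3p (−1.66 ± 0.33, adjusted p = 0.0337). In Dicer KO they lay at −0.13, −0.12 and 0.14, and in reads without additions the difference of miR-27a-3p was −0.80 (adjusted p = 0.342). The others were erythroid miR-486-5p (−1.18 ± 0.23, adjusted p = 0.0314), miR-22-3p (−1.005 ± 0.20, adjusted p = 0.0314; 0.69 and −0.31), miR-3535 (−3.96 ± 0.75, adjusted p = 0.0314; 4.58 and 0.62), whose lowest count was 2 reads, and miR-135a-2-3p (−2.42 ± 0.37, adjusted p = 0.0122). The last rose in Dicer KO (1.21 ± 0.26, adjusted p = 0.00759) and fell in DGCR8 KO (−1.22 ± 0.27, adjusted p = 0.0198), but in reads without additions it lay at −0.52 in Dicer KO (adjusted p = 0.206) and the difference was −0.48 (adjusted p = 0.614).

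The let-7 family fell less in DGCR8 KO than in Dicer KO, with a median difference of 0.64, 18 of 18 above 0, and 0 called members, 2 when adjusted over the list alone (adjusted p = 3.63e-05; adjusted p = 0.408 with an estimated correlation). The vessel and blood list had a median difference of −1.02 with 0 of 14 above 0, and 1 called member, 3 when adjusted over the list alone (adjusted p = 3.63e-05; adjusted p = 0.408 with an estimated correlation). The 12qF1 cluster did not differ past the threshold (−0.0380, adjusted p = 0.844), nor did the neuron-enriched (0.19), miR-9 and miR-125 (−0.12), miR-17-92 (0.0542) and choroid (−0.10) lists, each at an adjusted p = 0.844, or the repeat family (−0.11, adjusted p = 0.866). The medians of these 6 lists each changed sign in at least 1 omission, with no call in any. The posterior Hox, muscle, pluripotency and mesenchymal values were −0.71, −0.63, −0.35 and −0.74, with 0 calls. None of the 12 miRNAs kept its call in all 8 omissions of a compared library. The count was 0 without DGCR8 WT replicate 1, 2 without DGCR8 WT replicate 2, 7 without DGCR8 KO replicate 1, 6 without Dicer KO replicate 2, 8 without Dicer WT replicate 1 and 49 without Dicer KO replicate 1. Library totals gave 15 higher and 6 lower (median of all miRNAs moved by 0.18), factors from the vessel and blood list 99 and 1 (1.12), reads without additions 5 calls and DESeq2's test 38. With every library thinned to 800623 reads, 13 of 436 miRNAs were higher and 2 lower (0.13).

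**Figure D4:**
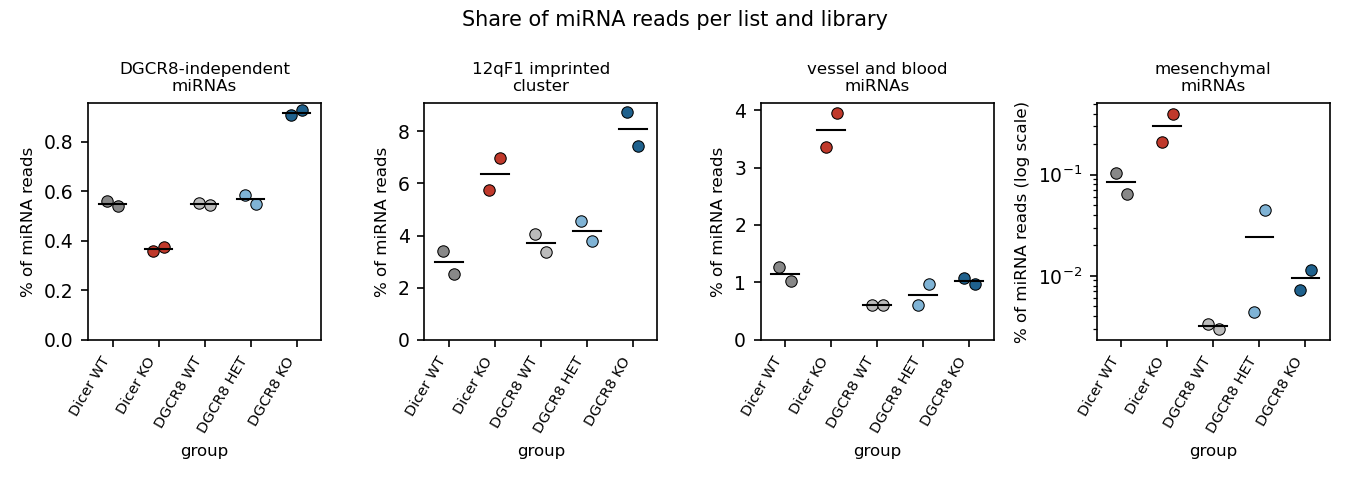
Percent of the miRNA reads of each library (vertical axes) taken by 4 lists, the mesenchymal one on a log scale, with points for the 2 libraries of a group and bars for their mean. DGCR8-independent miRNAs lie at 0.361% and 0.375% in Dicer KO and at 0.908% and 0.927% in DGCR8 KO, and mesenchymal miRNAs, a list added after seeing the data, at 0.00440% and 0.0444% in the DGCR8 HET mice.

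The wild types were compared to ask how far the libraries of the lines differ apart from the deletions. By the column names of the table the lines carry different numbers that may mark a pool or run, while the sample descriptions give the same number for both. A difference in batch therefore cannot be told apart from line in this contrast. The neuronal miR-153-3p was higher in DGCR8 WT than in Dicer WT (2.37 ± 0.22, adjusted p = 0.00105), as were miR-137-3p (1.84), miR-7b-5p (1.71), miR-7a-5p (1.29), miR-124-3p (1.22 ± 0.24, adjusted p = 0.0206) and miR-138-5p (0.95). The mesenchymal miRNAs were lower in DGCR8 WT, with miR-199b-3p at 576 ± 174 CPM in Dicer WT and 22.8 ± 4.83 CPM in DGCR8 WT (−4.65 ± 0.91, adjusted p = 0.0206). Of 557 miRNAs 42 differed, 15 higher and 27 lower in DGCR8 WT. All 5 mesenchymal miRNAs, a list chosen after seeing the data, were lower, also when adjusted over the list alone (median −5.08). Of these, miR-214-5p (−5.45), miR-214-3p (−5.42), miR-199a-5p (−5.08) and miR-199b-5p (−4.79) rest on few reads in DGCR8 WT, at most 15 per library. miR-455-3p (−3.90), miR-483-5p (−3.76), miR-10b-5p (−2.57), miR-205-5p (−2.01) and miR-574-3p (−1.95) were lower as well, and miR-3059-5p (2.11), miR-551b-3p (1.77), miR-344c-3p (1.31) and miR-136-3p (0.96) higher.

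Among the neuron-enriched miRNAs 7 of 22 were higher and 0 lower, or 8 and 0 when adjusted over the list alone (median 0.56, adjusted p = 1.53e-10; adjusted p = 0.116 with an estimated correlation). Of the vessel and blood miRNAs 7 of 14 were lower and 0 higher, or 11 and 0 when adjusted over the list alone (median −1.29, adjusted p = 1.61e-05), and miR-451a was among the lower (−1.31). Of the choroid plexus and epithelial miRNAs 1 of 12 was lower, also when adjusted over the list alone (median −1.74, adjusted p = 0.00282), but without Dicer WT replicate 2 the adjusted p = 0.0985. The 12qF1 median was 0.16 (5 higher, 9 when adjusted over the list alone, adjusted p = 6.42e-06), that of the miR-17-92 clusters −0.32 (adjusted p = 0.0393) and that of the repeat family −0.47 (adjusted p = 0.0460). These 5 lists each had an adjusted p = 0.499 with an estimated correlation. The DGCR8-independent (−0.12, adjusted p = 0.942), mirtron-numbered (−0.0879, adjusted p = 0.842), let-7 (−0.0595, adjusted p = 0.798) and miR-9 and miR-125 (−0.0572, adjusted p = 0.744) lists were not called and lay around 0, with signs that turned under other scalings. Without Dicer WT replicate 2 the let-7 median turned to 0.23 (adjusted p = 0.0476). The miR-17-92 call was lost without Dicer WT replicate 1 (−0.17, adjusted p = 0.238) or DGCR8 WT replicate 1 (−0.31, adjusted p = 0.0771), and the repeat call without Dicer WT replicate 1 (adjusted p = 0.238) or DGCR8 WT replicate 2 (adjusted p = 0.242). Both posterior Hox miRNAs were lower when adjusted over the list alone (median −2.45), and the muscle and pluripotency lists had 0 calls (0.55 and −0.54). Of the 21 named miRNAs only miR-153-3p kept its call in each omission of a wild-type library, and the others had an adjusted p of up to 0.231. The count was 1 without Dicer WT replicate 1, DGCR8 WT replicate 1 or DGCR8 WT replicate 2, and 27 without Dicer WT replicate 2. Library totals gave 25 higher and 21 lower (median of all miRNAs moved by 0.10), DESeq2 size factors 28 and 21 (0.13) and upper quartile factors 21 and 23 (0.12). Thinning every library to 800623 reads gave 12 higher and 15 lower among 436 (0.14).

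Bases added at the 3′ end were counted without regard to whether they match the genome, which the table does not say, so templated extension and tailing are counted as one. Reads with an addition made up 40.3% of miRNA reads in Dicer WT, 45.2% in Dicer KO, 37.9% in DGCR8 WT, 38.1% in DGCR8 HET and 36.7% in DGCR8 KO, as means of 2 libraries. Averaged over miRNAs these values were 38.2% in Dicer WT, 40.9% in Dicer KO and 38.7% in both DGCR8 WT and DGCR8 KO. A single added T was found on 13.7% and 14.2% of a miRNA's reads in the Dicer WT mice and 15.8% and 15.9% in the Dicer KO mice, averaged over 180 miRNAs. In DGCR8 WT it was 14.95% and 14.9%, in DGCR8 HET 14.9% and 14.7%, and in DGCR8 KO 15.4% and 15.4%. Taken over all reads together, in which a few abundant miRNAs weigh most, the T share was 20.9% and 18.5% in Dicer WT and 19.5% and 22.1% in Dicer KO, which overlap.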

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

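The tests of explanations given here, and the pattern in the vessel and blood list, were chosen only after the results were seen, while the contrast between the knock-outs and its lists were planned.

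The following results are given because the effect in the DGCR8 line differed from that in the Dicer line when the difference itself was tested. Higher in the DGCR8 KO effect were miR-6958-3p (2.95), miR-6944-3p (1.94), miR-702-3p (1.92), miR-1983 (1.82) and miR-484 (1.07). Lower were miR-22-3p (−1.005), miR-486-5p (−1.18), miR-27a-3p (−1.66), miR-24-2-5p (−1.70), miR-23a-3p (−1.77), miR-135a-2-3p (−2.42) and miR-3535 (−3.96). The lists that differed were the DGCR8-independent (1.15) and mirtron-numbered (1.45) lists, at adjusted p = 0.00891 and 0.0108 with an estimated correlation. The let-7 (0.64) and vessel and blood (−1.02) lists differed at the preset correlation alone, each with adjusted p = 0.408 with an estimated correlation.

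The DGCR8-independent miRNAs had 6 falls and 2 rises among 24 in Dicer KO (adjusted p = 0.0235, and 0.0530 without Dicer KO replicate 2; adjusted p = 0.209 with an estimated correlation) and, in the main fit, 4 rises, all of the miR-344 family, and 0 falls in DGCR8 KO (adjusted p = 0.0525 with an estimated correlation). Scaling moves all miRNAs alike and so cannot set a list apart from the others. The list's median difference lay 1.19 above that of the other miRNAs and at percentile 100 of 10000 random lists matched on expression. These values restate the list call, since that test already compares a list with the other miRNAs. A difference in depth is argued against. With every library thinned to 800623 reads the median of the 17 members then tested was 1.09 (adjusted p = 6.59e-06). Processing that needs Dicer but not DGCR8 stays open: in DGCR8 KO alone the list lay 0.56 above the other miRNAs, at percentile 98.8 of random lists, but without its 6 miR-344 members it lay 0.42 above them at percentile 91.9. The 2 rises in Dicer KO, miR-344d-3p (2.15) and miR-344f-3p (1.03), go against that explanation for these members. Without the family the median difference was 1.22 (adjusted p = 0.0122 with an estimated correlation), and shared reads and mouse line were not tested. The mirtron-numbered list, which holds no miR-344 member, had medians of −0.97 in Dicer KO and 0.48 in DGCR8 KO. With an estimated correlation these had adjusted p = 0.141 and 0.168, and this list was not set against random lists.

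The vessel and blood miRNAs rose in Dicer KO (median 1.44, adjusted p = 3.92e-06; adjusted p = 0.231 with an estimated correlation). Scaling moves all miRNAs alike and so cannot set this list apart from the others. The list's median lay 1.49 above that of the other miRNAs, at percentile 100 of random lists. Since the list test already compares a list with the other miRNAs, these values restate its call. A lower share of miRNA from the cells that lost Dicer could raise every other cell type alike. Of the gaps between other-tissue lists the largest against its error, posterior Hox against choroid, was 1.32 SE, or 1.24 on the log2 scale, so this cannot be told apart with 2 mice per group. Other tissue taken along at dissection stays open too, since the gap between the Dicer WT mice was 0.109 of the change between genotypes for this list but 2.24 for the choroid list.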

How the results depend on the processing

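The contrasts without DGCR8 HET replicate 2, where it is not compared, the fit without other-tissue lists, the thinned libraries (436 tested), the list without miR-344 members and the numbers shared by the knock-outs under other settings were chosen only after the results were seen. Of 1733 values of single miRNAs named in the text, under settings that keep all libraries, 147 lost and 36 gained a call and 11 reversed, and of 759 with a library left out 268 lost and 4 gained one. For lists 186 of 237 values kept direction and side of the threshold, 46 lost and 2 gained a call and 3 reversed, and with a library left out 238 kept both, 18 lost, 6 gained and 2 reversed. Unless the setting's construction shows it, as with suffix entries (2169 tested), no filter (1249 tested), reads without additions (455 tested), fits with fewer libraries, or factors that set the vessel and blood list level, the cause was not tested. The number of changed miRNAs is given here in percent of those tested, and a shift is named where the number itself moved by over 1.5 times. Percents cannot be compared between settings that tested different numbers, so the number of calls follows in brackets there, against 172, 115, 0, 48, 12 and 42 in the 6 contrasts. Dicer KO, 30.9%, was 19.03% with the lines fitted apart, 63.2% with factors from the vessel and blood list and 29.7% (645) with suffix entries tested alone, and 17.4% to 33.8% with a library left out. DGCR8 KO, 20.6%, was 7.002% with vessel and blood factors and 13.8% (300) with suffix entries, and 0.898% to 20.1%. HET, 0%, was 1.44% (18) with no filter, and 0% to 2.33%. DGCR8 KO against HET, 8.62%, was 13.6% on library totals, 5.03% on upper quartile factors, 6.81% (85) with no filter, 17.6% with the lines apart, 23.7% and 2.15% with factors from the DGCR8-independent and vessel lists, 7.56% (164) with suffix entries, 3.44% (15) in thinned libraries and 14.5% in DESeq2, and 0.898% to 9.69%. The difference between the knock-outs, 2.15%, was 3.77% on library totals, 4.16% (52) with no filter, 1.10% (5) in reads without additions, 17.95% with vessel factors, 3.92% (85) with suffix entries and 6.82% in DESeq2, and 0% to 8.80%. The wild types, 7.54%, gave 7.45% (93) with no filter, 5.30% (115) with suffix entries and 6.19% (27) in thinned libraries, and 0.180% to 9.69%. With the replicate block the 6 numbers of calls were 163, 88, 0, 48, 11 and 34. The 28 miRNAs higher in both knock-outs were 55 on library totals, 43 in DESeq2, 1 with factors from the vessel and blood list and 0 to 38 with a library left out, and the 37 lower in both were 9 on library totals, 24 on upper quartile factors, 24 in reads without additions, 18 in thinned libraries and 3 to 44. List calls, 32 of 60, were 2 with the correlation estimated, 23 by fry, 27 on library totals, 29 with the replicate block, and 29 to 33. Signs turned with factors from the vessel and blood list, which centre its members miR-451a and miR-486-5p near 0 by construction, for miR-22-3p (0.13 in the difference and −0.77 in Dicer KO) and in Dicer KO for miR-127-3p (−0.54), miR-434-3p (−0.56), miR-451a (−0.0494), miR-486-5p (−0.12), miR-26a-5p (−1.18), miR-124-3p (−0.92), miR-27a-3p (−1.31) and miR-135a-2-3p (−0.27, and −0.52 in reads without additions). On library totals miR-9 and miR-125 turned to 0.10 in DGCR8 KO and 0.0310 against HET, and the miR-17-92 clusters to 0.0445 against HET. With a library left out the vessel and blood median of DGCR8 KO against HET lay between −0.75 and 0.44, and the let-7 median between wild types between −0.28 and 0.23. In reads without additions, the DGCR8-independent share was 0.379% in Dicer KO, 0.535% in DGCR8 WT and 0.901% in DGCR8 KO. The 12qF1 share was 3.72%, 8.29%, 4.83%, 5.39% and 10.2% in Dicer WT, Dicer KO, DGCR8 WT, HET and KO. The vessel share was 0.495% in DGCR8 WT and 0.777% in DGCR8 KO, the choroid share 0.102% and the mesenchymal share 0.00278% in DGCR8 WT. The share with an addition, averaged over miRNAs, was 38.2%, 40.9%, 38.7% and 38.7% in Dicer WT, Dicer KO, DGCR8 WT and DGCR8 KO. Templated reads alone were not run, since the table does not mark them, nor was leaving out sequences listed under several names, since it holds no sequences. Depth limits the low-count miRNAs most, and Dicer KO libraries were the shallowest.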

Other observations

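All tests reported here were chosen only after the results were seen, apart from the shares of suffix classes.

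DGCR8 HET replicate 2 stood apart from replicate 1 in miRNAs of other tissues. Over the fixed other-tissue lists the median of replicate 1 lay 0.0636 above DGCR8 WT and that of replicate 2 lay 1.33 above it, on the log2 scale. A heterozygous effect common to both mice would not set them apart, so these values restate the pattern and are no separate test of that effect. An exchange with a library of the Dicer line is argued against, since it would leave a DGCR8 library under a Dicer name. On the first principal component the 4 Dicer libraries lay at −4.45 or below and the other 5 DGCR8 libraries at 6.58 or above. Replicate 2 itself lay between, at −0.400, and over the 42 miRNAs that differed between the wild types it lay at 0.517 on a scale from 0 at Dicer WT to 1 at DGCR8 WT (0.925 on the 15 higher and 0.291 on the 27 lower in DGCR8 WT), so a mixture or an outside sample stays open. Reads from other tissues stay open too: 28 of 29 members of those lists, or 96.6%, were higher in replicate 2, against 276 of 523 other miRNAs, or 52.8%, but this restates the pattern and cannot speak for an explanation.

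A hypothesis that the less abundant arm of a hairpin is lost sooner once processing stops was looked at, and no shift between the arms was found. The less abundant arm had the lower fold change in 52% of 150 pairs in Dicer KO and in 45.3% in DGCR8 KO (sign-flip permutation p = 0.643 and 0.801). Reads from cells that kept the gene would leave the ratio of the arms unchanged, and the share of such cells is not known. These values therefore cannot decide the hypothesis.

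The share of reads with a single added T rose in both knock-out mice over both wild types for 103 of 180 miRNAs in Dicer KO and fell for 18. If each miRNA varied on its own, 30 each way would be found by chance. All 180 were read in the same libraries, so a difference of whole libraries would move them together, and these numbers are not a test. Other classes moved as well in Dicer KO: 84 rose and 12 fell for 2 or 3 added T, 95 and 27 for other additions, and 21 and 97 for reads with no addition. For a single T the numbers in DGCR8 KO were 73 and 25, and in DGCR8 HET 26 and 36. The change in T share in Dicer KO went with that in DGCR8 KO across the 180 miRNAs, which are not independent replicates (r of 0.375, rho of 0.365, permutation p = 1e-05, the smallest they can give, adjusted p = 2e-05 over 2 relations). It did not go with the log2 fold change in Dicer KO past the threshold (r of −0.105, rho of −0.180, permutation p = 0.16, adjusted p = 0.16).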
